A study of Mus musculus with 8 samples.

How the data were processed

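RNA from splenic T cells of wild-type and Gfi1-knockout mice was measured on 8 Affymetrix MOE430A_2.0 arrays, 1 per genotype at 0, 4, 8 and 24 h of stimulation with antibodies against CD3 and CD28 (2 µg/ml). The T cells were enriched with a pan-T cell kit on an AutoMACS, RNA was extracted with TRIzol and biotin-labelled cRNA was made from about 1 µg. The deposited values are signal intensity, per the labels from GCOS 1.4 with MAS5; what each of these did to the values is not given in the sources used here. The deposited table held 22690 probe sets, 64 of them controls, and the 2% trimmed mean of each array was 1000.4 to 1000.5. All per-sample columns were used (0 unused).

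The signals were used as deposited. Values under a floor of 141.88 (log2 7.15), the median over arrays of each array's 40th percentile, were set to the floor and log2 was taken. Probe sets above the floor on at least 2 arrays were tested, 15062 of them. Of the probe sets, 20380 listed 1 gene symbol, 691 several and 1555 none; 20364 had an identifier in the reference table, 0 symbols were updated, and 12394 distinct genes were covered. Each of the 8450 tested genes was represented by its probe set with the highest mean. A difference against a value at the floor is a lower bound, and a difference in response that rests on such a value has no such bound.

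Genotypes were compared by size, as at least 2-fold in the same direction at all 4 times, with no p-value. Stimulation was tested in limma 3.58.1 under R 4.3.3, with time and genotype in the model, eBayes with a variance trend, an adjusted p under 0.05 and at least a 2-fold change. The fit left 3 residual degrees of freedom, with a median of 3.88 prior ones, and with 1 array per genotype and time this number limits the precision. A difference in response was the change in the knockout-labelled arrays minus that in the wild-type-labelled ones, by size, at least 4-fold. The 31 gene lists hold 470 genes, 389 of them tested. Lists were tested for stimulation by camera with a preset correlation of 0.01 and with an estimated correlation, 29 of them with enough genes, and placed for genotype among 10000 random lists drawn from 20 expression bins, between the 2.5th and 97.5th percentile. Genes are named by a fixed rule on the size of the difference and by list membership, except where the text says that they were chosen after their values were seen. Figures were drawn with matplotlib 3.10.9 from tables made with numpy 2.4.6 and pandas 2.3.3 under python 3.11.15.

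The steps were tested on simulated data with 200 changed among 15062 probe sets, 100 per size. The test of stimulation found 17% of changes of 1.5 and 74% of changes of 3 on the log2 scale, and called 4 unchanged probe sets. The genotype rule found 56% and 96% and called 6. The changes were placed only in probe sets with means far above the floor, and the noise was independent between arrays. The shares found therefore do not hold for probe sets near the floor. The calls of unchanged probe sets do not cover a difference between the sources of the arrays. The samples, the comparisons and the alternatives were chosen before the data were examined, apart from 1 alternative that takes differences relative to the T cell identity list. The alternatives were quantile normalization, each array divided by its median, floors at the 20th and 60th percentile, no filter, log2 of the signal plus the floor value, other fold thresholds, limma with time as a block for genotype, no genotype block, no variance trend, the median over a gene's probe sets, and leaving out each array or pair of arrays.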

Results

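RNA from mouse splenic T cells was measured on 8 Affymetrix MOE430A_2.0 arrays. The cells were enriched magnetically with a pan-T cell kit from wild-type and Gfi1-knockout C57Bl/6 mice. They were taken before stimulation or after 4, 8 and 24 h with antibodies against the T cell receptor component CD3 and the costimulatory receptor CD28. No array holds cells cultured for these times without the antibodies. A change from 0 h therefore joins the effects of the antibodies and of time in culture, which cannot be told apart here. Each genotype and time had 1 array, and the labels give 1 source number per genotype. No replicate therefore checks a difference between genotypes, and no p-value is given for one. The p-values given for stimulation set the change common to both genotypes against the difference between their responses in these samples. They measure no spread between animals or cultures of 1 genotype. Signals above the floor of 141.88 were seen for 56.5% to 61.5% of probe sets per array, and the median signal ran from 224 (wild-type-labelled, 24 h) to 305 (knockout-labelled, 0 h). The ratio of 3' to 5' signal was 0.725 to 0.939 for Gapdh and 1.11 to 1.28 for beta-actin, in each case highest in the wild-type-labelled 8 h array. The 5' probe set of 18S ribosomal RNA ranged from 947.5 (knockout-labelled, 0 h) to 37640 (knockout-labelled, 24 h), and the hybridisation control from 20389 to 39033.

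Gfi1, the zinc finger repressor that the mice are labelled as lacking, was higher in the knockout-labelled array at 0, 8 and 24 h and slightly lower at 4 h. Its probe set gave signals of 2316, 5979, 6459 and 9885 there at 0, 4, 8 and 24 h, against 882, 6359, 5259 and 3966 in the wild-type-labelled arrays. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here. Gfi1 therefore does not check the labels, and the arrays are called knockout-labelled and wild-type-labelled throughout. Xist, expressed from the inactive X chromosome, gave 7863 to 16762 over the 8 arrays in its probe set with the highest mean, while the Y-linked Eif2s3y, Kdm5d and Uty stayed under the floor on all 8. From 0 to 24 h Gfi1 rose by 2.13 on the log2 scale (SE 0.40, limma adjusted p = 0.0400, higher in both genotypes). The values at 4 h (2.11, adjusted p = 0.0704) and 8 h (2.03, adjusted p = 0.0582) did not pass in limma.

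The first comparison asks how the cells labelled as lacking Gfi1 differed from wild type before and during activation. Among marker genes of granulocyte precursors and of monocytes, 8 of 13 and 6 of 18 were at least 2-fold higher in the knockout-labelled array at all 4 times. The serine proteases Ctsg, Prtn3 and Elane and the peroxidase Mpo are proteins of the primary granules of neutrophil precursors. Ctsg gave 22212 against 1104 at 0 h and 1606 against 156 at 24 h, a mean log2 difference of 4.67 (SD over the 4 times 1.08). Prtn3, Elane and Mpo differed by 4.20, 3.99 and 3.83. The immunoglobulin Fc receptor subunit Fcgr3 was higher by 4.21, the membrane protein Ms4a3 by 4.04, the glutathione transferase Mgst1 by 4.16 and the lectin Clec5a by 3.92. The eosinophil granule protein Prg2 was higher by 3.83, Tgfbi by 3.84, Dmkn by 4.21 and the phospholipid-binding Anxa1 by 4.29. For all of these but Ctsg at least 1 wild-type-labelled signal was at the floor, so their differences are lower bounds.

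The 8 granulocyte markers that met this rule included S100a8, Lcn2, Mmp8 and Chil3 besides the primary granule genes. The list's median difference was 2.74, 4.20, 3.61 and 1.31 at 0, 4, 8 and 24 h, at the top of 10000 random lists matched on expression (percentile 100 at each time). Random lists draw genes independently and lack the correlation between members of a real list, so these percentiles are a description and not a test. At 24 h 12 of the 13 wild-type-labelled and 4 of the knockout-labelled signals were at the floor, which limits the 24 h median of the granulocyte list. Ngp, Camp and Ltf were not higher, with mean differences of -0.30, -0.22 and -0.28. Monocyte and macrophage markers had medians of 0.86, 1.49, 2.26 and 2.05, with 7 of 18 at least 2-fold higher at 0 h and 14 of 18 wild-type-labelled signals at the floor at 24 h. Cd14, the co-receptor for lipopolysaccharide, differed by 3.77 on average, Fcer1g by 3.57, the lysozyme Lyz2 by 3.46 and the receptor Csf1r by 3.42. The complement genes C1qa, C1qb and C1qc differed by 0.15, 0.00 and 0.19. The change of C1qa from 0 h, averaged over both genotypes, was -1.65 at each of 4, 8 and 24 h, as when both arrays are at the floor. Its differences at those times are then set by the floor, so its small mean does not show equal levels.

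**Figure D1:**
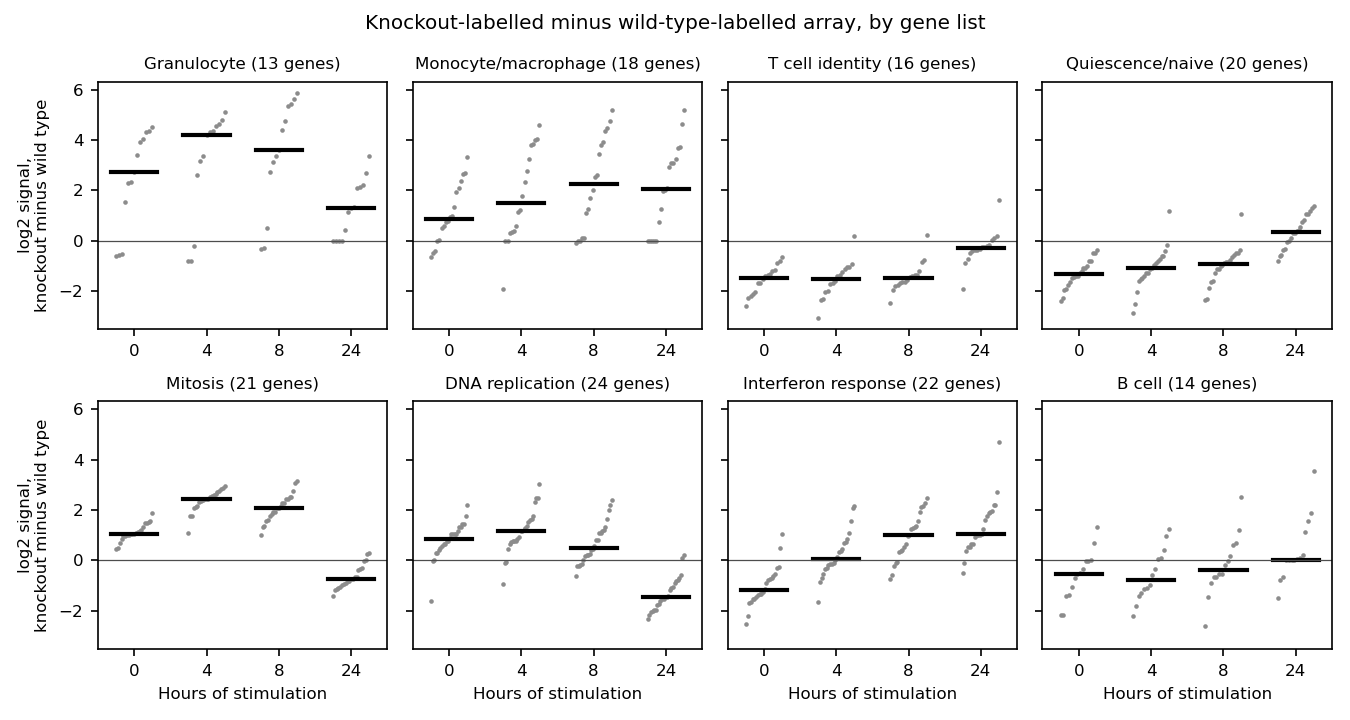
Log2 signal of the knockout-labelled minus the wild-type-labelled array (vertical axis) against hours of stimulation (horizontal axis) for 8 gene lists, with 1 point per gene and a bar at the list's median. Granulocyte medians lie at 1.31 to 4.20, T cell identity medians at -0.29 to -1.51, and DNA replication goes from 1.18 at 4 h to -1.46 at 24 h.

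Of the 16 T cell identity genes tested, 13, 14 and 13 were at least 2-fold lower in the knockout-labelled array at 0, 4 and 8 h and 1 at 24 h. Their median difference was -1.47, -1.51 and -1.5 at 0, 4 and 8 h and -0.29 at 24 h (percentiles 0, 0, 0 and 9.36), or -0.563 at 24 h with each array divided by its median. Cd3d, a chain of the T cell receptor complex, gave 7145 against 22780 at 0 h and 12672 against 14783 at 24 h. The adaptor Trat1 alone among the 16 was at least 2-fold lower at all 4 times, with a mean of -2.51. The CD8 lineage list of 4 genes had medians of -1.86, -1.07, -1.24 and -0.09 (-0.196 and -0.362 at 24 h under the 2 other scalings), with Cd8a at -2.25 and Cd8b1 at -2.03 at 0 h. The CD4 lineage list of 3 genes had 0.00, -0.54, 0.00 and 0.00, with Cd4 itself at -1.79, -2.05, -1.10 and -0.74. Genes of naive and resting T cells (20 tested) were lower as well, with medians of -1.33, -1.10 and -0.91 and then 0.36 at 24 h (0.079 with each array divided by its median). Lef1, a transcription factor of naive T cells, differed by -2.28, -2.06, -2.34 and -0.82, and Bach2 by -1.94, -1.62, -1.87 and 0.10. None of the 20 met the rule. The granulocyte and monocyte markers were higher in the same arrays.

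B cell markers (14 tested) had medians of -0.52, -0.76, -0.36 and 0.04, with 5, 6, 2 and 1 at least 2-fold lower and 1, 1, 2 and 4 at least 2-fold higher. Ms4a1, the B cell antigen CD20, met the rule with a mean of -2.12, while Jchain, the joining chain of secreted immunoglobulin, was higher by 0.68, 0.98, 2.53 and 3.54. Red cell genes (5 tested) had medians of 0.19, -0.06, 0.08 and -0.56 (-0.185 and 0.186 at 4 and 8 h with quantile normalization), and the carbonic anhydrase Car1 stood at -3.13 at 24 h. Dendritic cell markers (5 tested) had 0.00, -0.19, -0.80 and 0.11 (-0.239, -0.472 and 0.033 at 0, 8 and 24 h with each array divided by its median), with the chemokine Ccl22 at -1.99 at 8 h and -2.49 at 24 h. Platelet markers (4 tested) had -0.35, -0.10, 0.01 and 0.69 (-0.05 at 8 h with each array divided by its median, and 0.00 at 0 h and -0.155 and -0.176 at 4 h under the 2 other scalings), with Itga2b at 1.13 at 24 h. Of 10 natural killer cell genes only Klra7 was tested, with a mean of -0.56. Its signal was at the floor in every knockout-labelled array and in the wild-type-labelled 24 h array, which limits this mean. Of the sex-linked genes only Xist was tested, with a mean of -0.28.

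Il4 and Il17a differed in opposite directions after stimulation. Il4, the signature cytokine of type 2 helper cells, reached 8656, 5019 and 1884 at 4, 8 and 24 h in the wild-type-labelled arrays but 190, 126 and 422 in the knockout-labelled ones. The difference at 4 h was -5.51, and at 0 h it was -0.84, so that Il4 did not meet the rule at all 4 times. Il17a, the signature cytokine of Th17 cells, gave 16998, 14264 and 14177 in the knockout-labelled arrays against 1627, 941 and 627, a mean difference of 3.30 that held the rule at all 4 times. The Th2 list (8 tested) had medians of 0.00, -1.23, -1.04 and 0.03 (-0.07 and -0.09 at 24 h under the 2 other scalings), and 0 of 8 met the rule, with the lineage factor Gata3 at -2.97 at 8 h. Th17 genes (6 tested) had 0.00, 0.97, 0.58 and 2.00, and Il17a was the 1 member that met the rule. The cytokine list as a whole (24 tested) had medians of -0.01, 0.38, -0.03 and 0.68 (0.242 and 0.399 at 4 and 24 h with each array divided by its median), and 1 of 24 met the rule. The 0 h medians of these 3 lists are limited by the floor and do not show equal levels. In the knockout-labelled and wild-type-labelled 0 h arrays 6 and 5 of 8 Th2, 2 and 4 of 6 Th17 and 13 and 11 of 24 cytokine signals were at the floor. Regulatory T cell genes (12 tested) had -0.75, -0.74, -0.23 and 1.09. Gpr83 (mean -2.06) and Izumo1r (mean -1.57) were lower at all 4 times.

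Of 19 tested genes linked to memory and effector T cells, several of them also abundant in myeloid cells, 7 were at least 2-fold higher at all 4 times. The list had medians of 0.39, 1.26, 1.2 and 1.92. After Anxa1 they included the calcium-binding S100a6 (2.99), Anxa2 (2.63) and the intermediate filament Vim (2.57). Cytotoxic genes (17 tested) had -0.35, -0.19, 0.03 and 0.88 (-0.04 at 8 h with each array divided by its median, and -0.319 and -0.327 at 4 h under the 2 other scalings), with the receptor Klrc1 at 4.03 and the chemokine Ccl5 at 3.60 at 24 h. The inhibitory receptor list (7 tested) had -0.23, -0.52, -0.55 and 0.06 (0.137 at 24 h with quantile normalization), with Havcr2 at 2.47 at 24 h and Tox at -1.39 on average. Of 22 tested genes listed as known or proposed targets of Gfi1, 5 were higher at all times and 1 was lower, with list medians of 0.31, 0.18, 0.35 and 1.25 (0.116 and 0.104 at 4 h under the 2 other scalings). The higher ones, Elane (3.99), Csf1r (3.42), the myeloid factors Spi1 (2.84) and Cebpa (2.19) and Hoxa9 (2.23), are myeloid or progenitor genes, and the lower one was Egr2 (-1.60). The granulocyte and monocyte markers were higher in the same arrays, and Elane and Csf1r belong to those lists too.

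The medians of proliferation genes changed sign between 8 and 24 h. Mitosis genes (21 tested) were higher in the knockout-labelled arrays by medians of 1.07, 2.45 and 2.10 at 0, 4 and 8 h and had a median of -0.74 at 24 h. Of the 21, 15 were at least 2-fold higher at 0 h and 21 at 4 and 8 h, and 5 were at least 2-fold lower at 24 h. The kinase Aurkb stood at 2.78 at 8 h and -0.91 at 24 h. DNA replication genes (24 tested) had medians of 0.84, 1.18, 0.51 and -1.46, and 17 of the 24 were at least 2-fold lower at 24 h. The replicative helicase subunit Mcm5 gave 1050 against 5283 at 24 h, and the ribonucleotide reductase subunit Rrm2 differed by 2.41 at 8 h and -0.89 at 24 h. Ribosome biogenesis genes (19 tested) had 0.27, -0.80, -0.59 and -0.84, with Gnl3 at -0.95 and Polr1b at -0.92 on average. Amino acid supply and stress genes (18 tested) had 0.10, -0.43, -0.61 and -1.08, with the stress factor Ddit3 at -0.98 on average. Cholesterol synthesis genes (14 tested) had -0.32, 0.29, 1.16 and -0.60 (0.152 at 4 h with each array divided by its median), with the enzyme Fdps at 2.36 at 8 h. Markers of cell types moved between the same arrays. The median difference of granulocyte markers went from 3.61 at 8 h to 1.31 at 24 h and that of T cell identity genes from -1.5 to -0.29. From 0 to 24 h granulocyte markers changed by a median of -3.79 in the knockout-labelled and -2.80 in the wild-type-labelled arrays, beside -2.51 and -0.68 for mitosis genes. The granulocyte values at 24 h are limited by the floor, at which 12 of the 13 wild-type-labelled signals stood.

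Of 22 interferon response genes tested, 12 were at least 2-fold lower at 0 h (list median -1.18) and 11 and 14 at least 2-fold higher at 8 and 24 h (medians 1.00 and 1.05). At 4 h the median was 0.08, or 0.241 with quantile normalization and -0.06 with each array divided by its median. The guanylate-binding protein Gbp3 was the 1 member higher at all times (mean 1.19). Between the same arrays monocyte markers had medians of 0.86, 1.49, 2.26 and 2.05 at 0, 4, 8 and 24 h. T cell identity genes had -1.47, -1.51, -1.5 and -0.29. Glycolysis genes (14 tested) had medians of 0.52, 0.19, 0.18 and 1.09 (0.059 and 0.106 at 4 and 8 h with each array divided by its median), and Tpi1, an enzyme of the pathway, was higher throughout (mean 1.69). Early activation genes (24 tested) had 0.00, -1.07, -0.61 and 0.14 (-0.06 at 24 h with each array divided by its median), with Egr2 lower throughout. Genes of NF-kB signalling and survival (15 tested) had -0.81, -0.40, -0.23 and 0.63 (-0.237 at 4 h with quantile normalization and 0.357 at 24 h with each array divided by its median), with Bcl3 at 0.71 on average. The p53 response list (14 tested) had -0.07, 0.03, -0.03 and 0.84 (-0.11 and -0.105 at 4 and 8 h with each array divided by its median), with the cell cycle inhibitor Cdkn1a at 2.23 at 24 h. Heat shock genes (10 tested) had -0.26, -0.32, -0.43 and -0.23 (-0.022 at 0 h with quantile normalization, and -0.409 and -0.504 at 24 h under the 2 other scalings), with Hsph1 at -0.97 on average.

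In all, 240 of 15062 probe sets (157 of 8450 genes) were at least 2-fold higher in the knockout-labelled array at all 4 times and 23 (14 genes) were lower. The lower genes with the largest mean differences after Trat1 were Patj (-2.24), Itm2a (-2.16), Ms4a1, Gpr83, the sodium pump subunit Atp1b1 (-2.06), Tspan9 (-2.02), Sh3gl3 (-1.84, with all knockout-labelled signals at the floor), Egr2, Izumo1r, Lad1 (-1.5) and Evl (-1.49). Relative to the T cell identity list, an alternative chosen after the result was seen, 1339 probe sets met the rule as higher and 0 as lower, so that 0 of the 23 were shared. That list's median difference was negative at all 4 times, so this alternative raises every difference by construction. By the mean over times, 9 lists lay above and 7 below the central range of random lists, whose genes are drawn independently. At single times 1126 probe sets were higher and 1055 lower at 0 h, 1555 and 1023 at 4 h, 1559 and 1020 at 8 h, and 1259 and 733 at 24 h. Differences correlated across genes at r = 0.64 between 0 and 4 h and 0.81 between 4 and 8 h, but 0.10 between 0 and 24 h. Genes are not independent replicates. Without the 0 h pair of arrays the rule was met by 435 higher and 56 lower, without the 4 h pair by 249 and 29, without the 8 h pair by 261 and 32 and without the 24 h pair by 535 and 200. Dividing each array by its median moved the median of all tested probe sets from 0.00 to -0.19 at 24 h, from -0.02 to -0.15 at 4 h and from -0.07 to -0.16 at 8 h. Relative to that scale the rule was met by 196 and 47, with 1365 and 1474 at 4 h and 898 and 1599 at 24 h.

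**Figure D2:**
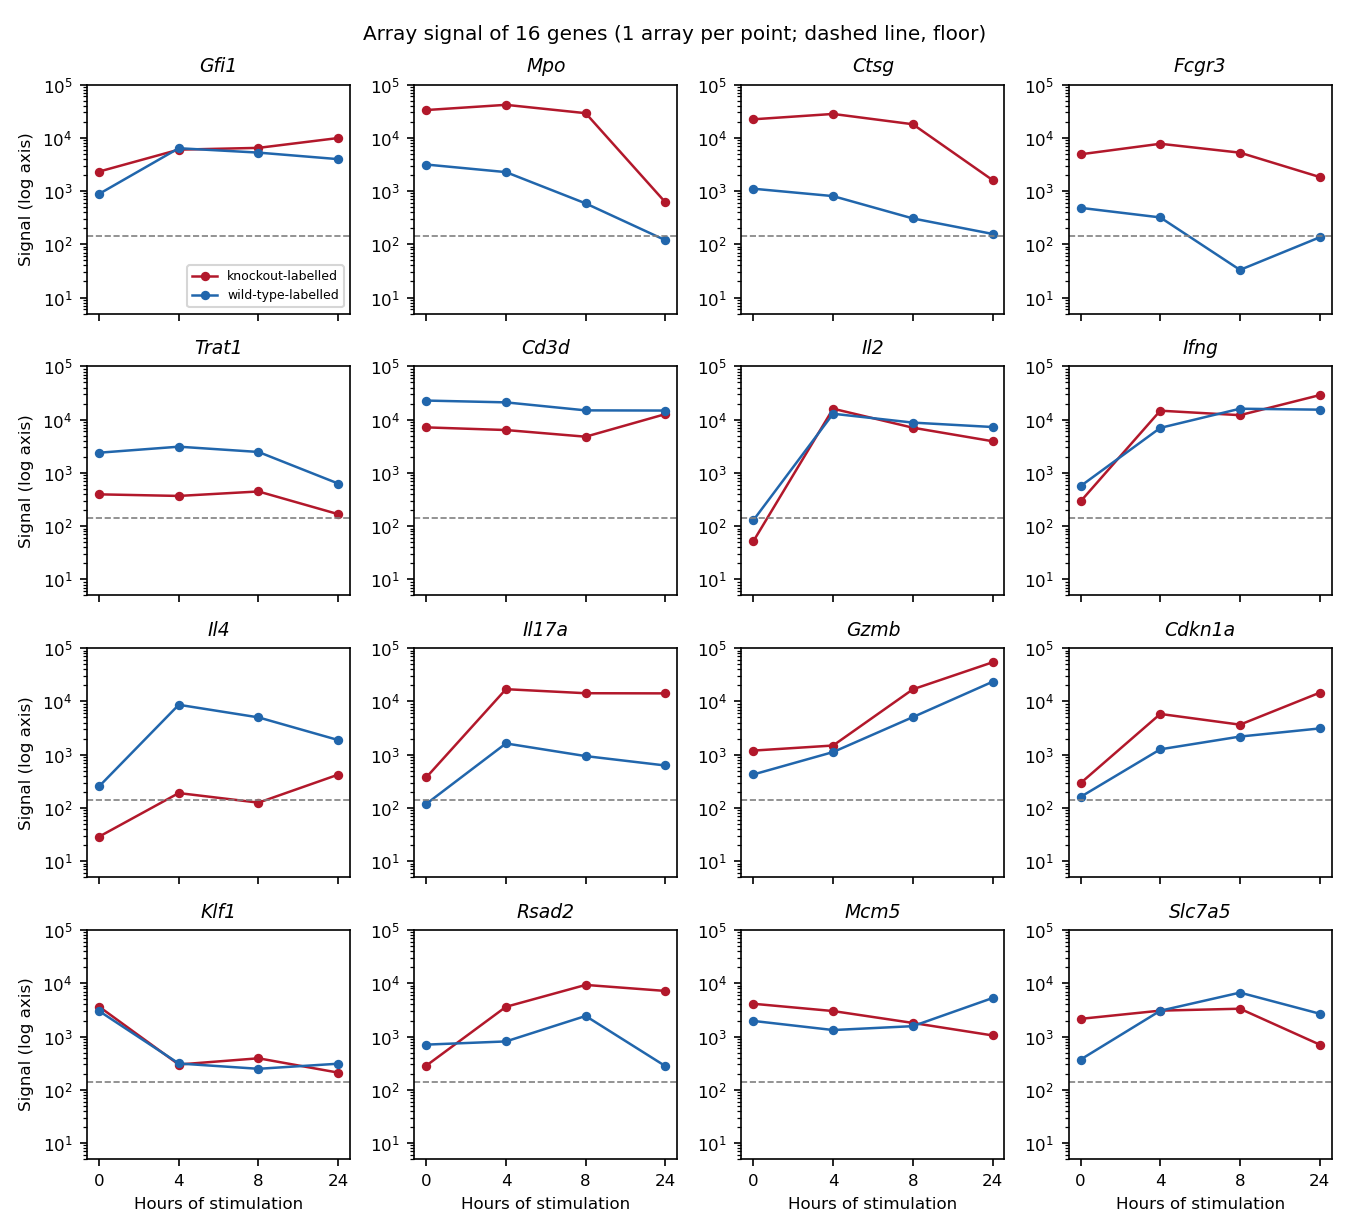
Array signal (vertical log axis) against hours of stimulation (horizontal axis) for 16 genes, with 1 array per point and the floor as a dashed line. Gfi1 is 2316 and 882 at 0 h in the knockout-labelled and wild-type-labelled arrays, Mpo 33134 and 3142, and Il4 at 4 h 190 and 8656.

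The second comparison asks what changed from 0 to 4 h of stimulation, time in culture included, on average over both genotypes. Of the 24 cytokine genes tested, 14 rose. Il2, the growth factor of activated T cells, rose by 6.66 on the log2 scale (SE 0.31, limma adjusted p = 0.00107, higher in both genotypes), from 52.1 and 129, both under the floor, to 16012 and 12882. Setting both 0 h signals to the floor removed the spread between them, so the SE and p can be too small. The same holds wherever both arrays of a time are at the floor. Among the 24 cytokine genes, 13 were at the floor in the knockout-labelled and 11 in the wild-type-labelled 0 h array. The interferon-induced chemokine Cxcl10 rose by 6.67, Cxcl9 by 6.15, the chemokine Ccl3 by 5.77, the stress factor Atf3 by 5.07, Tnf by 5.0, Sema7a by 4.67 and Ifng by 4.65, with limma adjusted p from 0.00107 to 0.0203. Among the 8 genes that fell most was Klf1, 1 of 2 called among the 5 red cell genes tested. The water channel Aqp1 changed by -3.94 (SE 0.32, limma adjusted p = 0.00991), the blood group protein Ermap by -3.60, the erythroid factor Klf1 by -3.44, the iron exporter Slc40a1 by -3.44 and the Rh-associated glycoprotein Rhag by -3.03. The others were Dtx1 (-3.31), C1qtnf12 (-3.02) and the kinase Sphk1 (-2.90).

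Adjusted over the list alone 18 of the 24 cytokine genes rose at 4 h, with a median of 2.94 (camera adjusted p = 6.34e-27, and adjusted p = 0.354 with an estimated correlation). Early activation genes rose by a median of 1.74 (6 of 24 passed, 12 adjusted over the list alone), with Irf4 at 4.64, Egr2 at 4.55, Nr4a2 at 4.16 and Nr4a1 at 3.74. Camera gave an adjusted p = 6.53e-17, and adjusted p = 0.354 with an estimated correlation. NF-kB and survival genes had a median of 1.76 (4 of 15, 12 adjusted over the list alone; camera adjusted p = 1.79e-16, and adjusted p = 0.354 with an estimated correlation), led by Icam1 at 3.18, Nfkb2 at 2.84, Relb at 2.77 and Birc3 at 2.5. Interferon response genes had 1.73 (8 of 22, 10 adjusted over the list alone; camera adjusted p = 3.74e-15, and adjusted p = 0.534 with an estimated correlation), with Iigp1 at 4.65, Gbp2 at 4.41 and Socs1 at 3.53. Amino acid supply and stress genes had 1.60 (5 of 18, 12 adjusted over the list alone; camera adjusted p = 2.14e-15, and adjusted p = 0.354 with an estimated correlation), with Chac1 at 3.14, Trib3 at 2.74, Mthfd2 at 2.52 and the amino acid transporter chain Slc3a2 at 1.83.

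Smaller shifts at 4 h passed camera for ribosome biogenesis (median 0.49, 0 of 19 genes; adjusted p = 3.99e-05, and adjusted p = 0.626 with an estimated correlation). Its median change was -0.135 in the knockout-labelled and 1.02 in the wild-type-labelled arrays, and without the wild-type-labelled 0 h array the common median was -0.0752. Th2 genes had 1.01 (0 of 8, 3 adjusted over the list alone; camera adjusted p = 0.000444, and adjusted p = 0.626 with an estimated correlation). Th17 genes had 1.11 (1 of 6, Il17a at 4.51, and 3 adjusted over the list alone; camera adjusted p = 0.00395, and adjusted p = 0.442 with an estimated correlation). Regulatory T cell genes had 0.80 (1 of 12, the receptor chain Il2ra at 3.47, and 3 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.626 with an estimated correlation). Lists that camera placed lower were red cell genes (median -2.42, 2 of 5, Klf1 and Car2 at -2.42, and 3 adjusted over the list alone; adjusted p = 0.00104, and adjusted p = 0.354 with an estimated correlation). Camera also placed lower DNA replication (median -0.89, 0 of 24; adjusted p = 0.0131, and adjusted p = 0.752 with an estimated correlation) and B cell markers (median -0.59, 1 of 14, Cd22 at -1.77; adjusted p = 0.0176, and adjusted p = 0.626 with an estimated correlation). T cell identity genes had a median of 0.12 (1 of 16, the adaptor Lcp2 at 2.00, camera adjusted p = 0.389), and granulocyte markers -0.11 (0 of 13, camera adjusted p = 0.949). With each array divided by its median the T cell identity median was 0.303 and the granulocyte median 0.08.

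At 4 h limma called 95 probe sets (68 genes) higher and 70 (53 genes) lower, of 2043 with an unadjusted p under 0.05. Camera placed 9 of 29 lists higher and 3 lower, and 0 held with an estimated correlation. Without either 0 h array or either 4 h array limma called 0 and 0, without either 8 h array 5 and 0, without the knockout-labelled 24 h array 169 and 89, and without the wild-type-labelled one 175 and 91. The calls were 97 and 45 with quantile normalization and 132 and 45 with each array divided by its median, which moved the median change of all probe sets from -0.09 to 0.05.

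**Figure D3:**
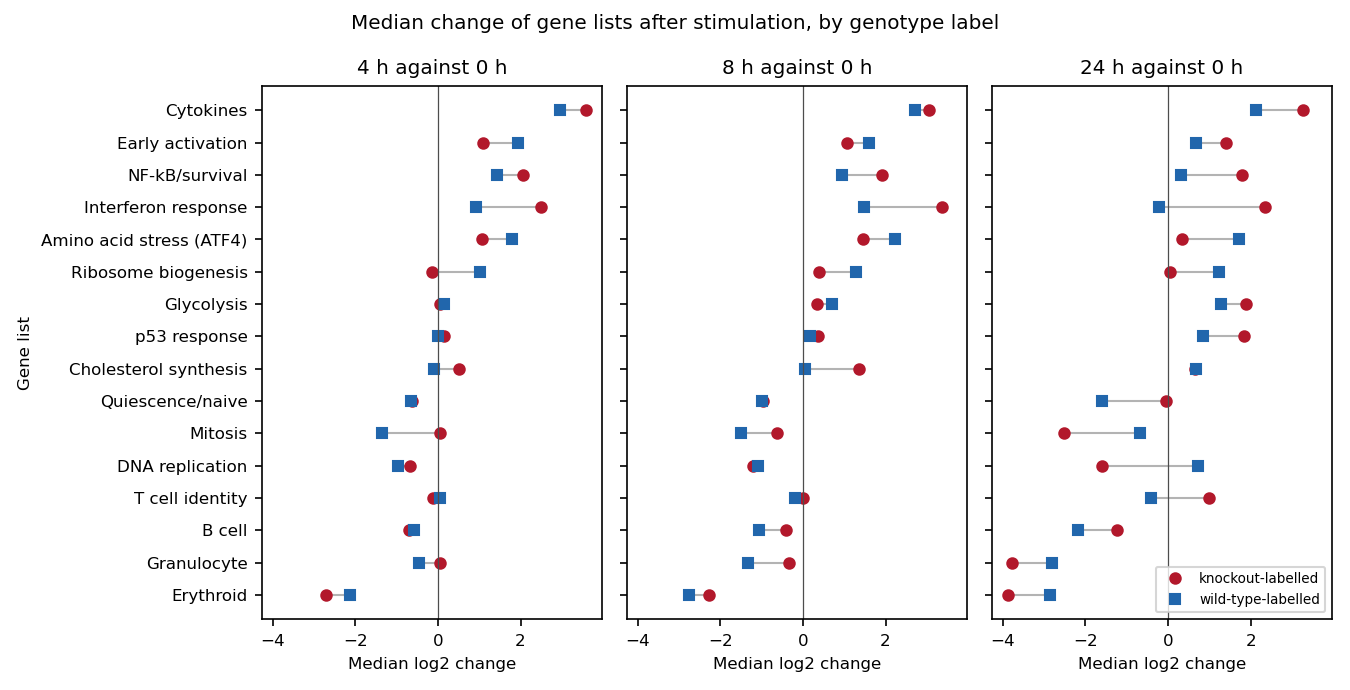
Median log2 change from 0 h (horizontal axis) of 16 gene lists (vertical axis) at 4, 8 and 24 h, with 1 symbol per genotype label. Cytokine medians lie at 3.60 and 2.96 at 4 h in the knockout-labelled and wild-type-labelled arrays, and DNA replication medians at -1.60 and 0.72 at 24 h.

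After 8 h 13 of the 24 cytokine genes were higher. Cxcl10 rose by 6.09, Cxcl9 by 6.03, Ccl3 by 5.88 (SE 0.26, limma adjusted p = 0.00172, higher in both genotypes), Il2 by 5.79, Ifng by 5.10, the transaminase Bcat1 by 4.77, the transcription factor Irf4 by 4.68 and the interferon-induced GTPase Iigp1 by 4.55. Aqp1 (-3.98), Ermap (-3.93), Slc40a1 (-3.44) and Klf1 (-3.42) were lower, together with the hydroxylase Cmah (-3.55), C1qtnf12 (-3.38), Dtx1 (-3.30) and the T cell surface protein Cd7 (-3.23), at limma adjusted p from 0.00483 to 0.0228. Gzmb, a protease of cytotoxic granules, rose by 3.70 and the inhibitory receptor Lag3 by 2.2.

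At 8 h interferon genes had a median of 2.46 (8 of 22, 20 adjusted over the list alone; camera adjusted p = 1.39e-18, and adjusted p = 0.488 with an estimated correlation). Cytokines had 2.72 (13 of 24, and 18 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.25e-19, and adjusted p = 0.488 with an estimated correlation). Amino acid genes had 1.84 (6 of 18, 15 adjusted over the list alone), NF-kB genes 1.79 (5 of 15, 10 adjusted over the list alone) and early activation genes 1.4 (7 of 24, 13 adjusted over the list alone), with camera adjusted p of 5.78e-15, 1.28e-11 and 8.84e-11, and adjusted p = 0.488 with an estimated correlation for all 3. Ribosome biogenesis (median 0.87, 0 of 19, 6 adjusted over the list alone), cholesterol synthesis (0.61, 0 of 14, 4 adjusted over the list alone), glycolysis (0.46, 1 of 14, the hexokinase Hk2 at 2.41, 2 adjusted over the list alone), Th2 (1.14, 0 of 8), p53 response (0.16, Cdkn1a at 3.71 and Sesn2 at 2.27 of 14, and 4 higher and 1 lower adjusted over the list alone) and regulatory T cell genes (0.72, 1 of 12, and 2 higher and 1 lower adjusted over the list alone) were also higher by camera. Their adjusted p were 9.14e-09, 0.000449, 0.00463, 0.00264, 0.0285 and 0.0182, and adjusted p = 0.658 with an estimated correlation for each. With each array divided by its median the glycolysis median was 0.713 and the p53 median 0.414. The p53 median was -0.0844 without the wild-type-labelled 8 h array and -0.0046 without the knockout-labelled 0 h array. The cholesterol median was 1.35 in the knockout-labelled and 0.046 in the wild-type-labelled arrays, and that of regulatory T cell genes 1.11 and 0.307.

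Camera placed 7 lists lower at 8 h. Red cell genes had a median of -2.52 (2 of 5, 3 adjusted over the list alone; adjusted p = 0.00463, and adjusted p = 0.488 with an estimated correlation). Mitosis (-1.07, 0 of 21), DNA replication (-1.16, 0 of 24), B cell markers (-0.67, 2 of 14), granulocyte markers (-0.81, 0 of 13), memory genes (-1.2, 0 of 19, and 1 higher and 9 lower adjusted over the list alone) and resting T cell genes (-0.98, 1 of 20, Rasgrp2 at -2.97, and 1 higher and 9 lower adjusted over the list alone) had camera adjusted p of 0.00455, 0.00455, 0.00633, 0.0443, 0.0443 and 0.0443, and adjusted p = 0.658 with an estimated correlation for each. With each array divided by its median the B cell median was -0.355. The memory genes had medians of -0.328 in the knockout-labelled and -1.92 in the wild-type-labelled arrays, and the granulocyte markers -0.337 and -1.34. In total limma called 144 probe sets (100 genes) higher and 149 (106 genes) lower, of 2986 with an unadjusted p under 0.05, and camera placed 11 lists higher. Of the lists placed higher or lower, 0 held with an estimated correlation. Without either 0 h or either 8 h array limma called 0 and 0, without either 4 h array 2 and 0, without the knockout-labelled 24 h array 286 and 368, and without the wild-type-labelled one 279 and 343. Camera placed 4 lists lower without the knockout-labelled 0 h array, 2 without the wild-type-labelled 0 h array and 3 without the wild-type-labelled 8 h array. The calls were 145 and 94 with quantile normalization and 211 and 94 with each array divided by its median, which moved the median change from -0.10 to 0.10.

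By 24 h cytokine genes (14 of 24) and glycolysis genes (7 of 14) rose, and markers of granulocytes (8 of 13), B cells (6 of 14), monocytes (5 of 18) and red cells (3 of 5) fell. Ccl3 rose by 6.40 (SE 0.26, limma adjusted p = 0.00097, higher in both genotypes), Ifng by 5.70, Gzmb by 5.64, Il2 by 5.23, Cdkn1a by 4.96, Irf4 by 4.58, Il2ra by 4.49 and the chemokine Ccl4 by 4.28. The immunoglobulin genes Igha, Igk and Igkv14-111 changed by -5.96, -4.86 and -4.43, the myeloid genes Mpo, S100a9, S100a8 and Elane by -5.11, -5.05, -4.89 and -4.40, and Car1 by -4.61, with limma adjusted p from 0.00818 to 0.0485. Granulocyte markers had a median of -3.30 (8 of 13 passed, 10 adjusted over the list alone; camera adjusted p = 2.84e-08, and adjusted p = 0.429 with an estimated correlation). B cell markers had -1.65 (6 of 14, 10 adjusted over the list alone; camera adjusted p = 1.03e-07, and adjusted p = 0.429 with an estimated correlation). Monocyte markers had -1.54 (5 of 18, 11 adjusted over the list alone; camera adjusted p = 0.000383, and adjusted p = 0.459 with an estimated correlation). Red cell genes had -3.38 (3 of 5, 3 adjusted over the list alone; camera adjusted p = 0.00171, and adjusted p = 0.429 with an estimated correlation).

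Glycolysis genes rose at 24 h over both genotypes by a median of 1.56 (7 of 14, 9 adjusted over the list alone), with Hk2 at 2.82, Tpi1 at 1.88, Pkm at 1.80 and Pfkp at 1.78 (camera adjusted p = 3.71e-09, and adjusted p = 0.429 with an estimated correlation). The p53 response list had 1.28 (5 of 14 higher and Gadd45a lower; 8 and 1 adjusted over the list alone), with Phlda3 at 3.34 and Zmat3 at 2.59 (camera adjusted p = 9.32e-07, and adjusted p = 0.459 with an estimated correlation). Cytokines had a median of 2.67 (14 of 24, and 17 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.21e-17, and adjusted p = 0.429 with an estimated correlation). Early activation genes had 1.14 (6 higher and 1 lower of 24, 11 and 1 adjusted over the list alone; camera adjusted p = 9.32e-07, and adjusted p = 0.459 with an estimated correlation). NF-kB genes had 0.94 (3 of 15, 6 adjusted over the list alone; camera adjusted p = 9.32e-07, and adjusted p = 0.459 with an estimated correlation). Amino acid genes had 0.95 (2 of 18, 7 adjusted over the list alone) and ribosome biogenesis 0.72 (0 of 19), both at camera adjusted p = 1.18e-06 and at adjusted p = 0.429 and adjusted p = 0.486 with an estimated correlation. Interferon genes had 0.88 (5 of 22, 7 adjusted over the list alone; camera adjusted p = 1.03e-07, and adjusted p = 0.486 with an estimated correlation). Th2 genes had 2.23 (0 of 8, 4 adjusted over the list alone; camera adjusted p = 0.000162, and adjusted p = 0.459 with an estimated correlation). Cholesterol synthesis had 0.70 (1 of 14, Idi1 at 2.13, 2 adjusted over the list alone; camera adjusted p = 0.00525, and adjusted p = 0.572 with an estimated correlation). Regulatory T cell genes had 0.47 (2 of 12, with Tnfrsf18 at 3.31, and 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0153, and adjusted p = 0.559 with an estimated correlation), 0.717 with each array divided by its median and -0.0284 without the knockout-labelled 24 h array. Some of these medians came mainly from 1 genotype. Interferon genes changed by 2.35 in the knockout-labelled and -0.217 in the wild-type-labelled arrays, regulatory T cell genes by 1.28 and -0.09 and NF-kB genes by 1.79 and 0.316. Ribosome biogenesis genes changed by 0.058 and 1.24 and amino acid genes by 0.343 and 1.71.

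Mitosis genes at 24 h had a median of -1.51 (0 of 21, 1 lower adjusted over the list alone; camera adjusted p = 4.11e-05, and adjusted p = 0.558 with an estimated correlation). Resting T cell genes had -0.88 (4 of 20 lower, and 3 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.656 with an estimated correlation), with Rasgrp2 at -4.08, the migration factor Klf2 at -3.52, Tsc22d3 at -3.20 and Klf3 at -2.46. With each array divided by its median the resting T cell median was -0.588. It was -0.047 in the knockout-labelled and -1.61 in the wild-type-labelled arrays, and the mitosis median -2.51 and -0.68. Lists that did not pass camera at 24 h were the Gfi1 target list (median -0.42, adjusted p = 0.247), DNA replication (-0.49, 0.326), cytotoxic genes (-0.11, with Gzmb as the 1 call, 0.962), memory genes (-0.60, with S100a4 at -3.26 and Ccr2 at -2.81, 0.0619), Th17 (-0.11, with Il17a at 3.69 and Il21 at 2.96, 0.142) and T cell identity (0.17, 0.156). With each array divided by its median the Gfi1 target median was -0.176, DNA replication -0.193, memory genes -0.303 and T cell identity 0.466. The T cell identity median was 0.02 with quantile normalization. Adjusted over the list alone 3 Gfi1 targets were higher and 8 lower, 2 memory genes higher and 8 lower, and 2 cytotoxic genes and 2 T cell identity genes higher with 1 lower in each. The DNA replication median was 0.672 without the knockout-labelled 24 h array, and that of Th17 was 0.405 without the wild-type-labelled 0 h array and 0.892 without the wild-type-labelled 24 h array. Nor did camera pass the CD4 (-0.09, adjusted p = 0.65) and CD8 lineage (0.34, 0.302), inhibitory receptors (1.09, with Lag3 at 3.82, 0.0562), heat shock (0.10, with Hspa1b at -2.14 and Hspa1a at -2.01, 0.568), dendritic (-0.47, 0.784) and platelet markers (0.56, 0.0785). Adjusted over the list alone 3 inhibitory receptors were higher and 1 lower, 1 dendritic marker higher and 1 lower, and 1 CD8 lineage gene and 1 platelet marker higher. The median was negative while the mean was positive for the cytotoxic list (-0.11 and 0.06, camera up), Th17 (-0.11 and 0.96, camera up) and dendritic markers (-0.47 and 0.14, camera down), and the reverse held for heat shock (0.10 and -0.38, camera down). At 4 h signs also differed for the Gfi1 targets (-0.22 and 0.27, camera up), the cytotoxic list (-0.19 and -0.03, camera up), the CD8 lineage (-0.13 and 0.28, camera up) and dendritic markers (-0.44 and 0.27, camera down). At 8 h they differed for the Gfi1 targets (-0.47 and -0.01, camera up), the CD8 lineage (-0.16 and 0.27, camera up), dendritic markers (-0.08 and 0.64, camera up) and platelet markers (-0.02 and -0.13, camera up). The dendritic medians at 4, 8 and 24 h and the platelet median at 8 h were positive under both other scalings, as was the cytotoxic median at 24 h. The CD8 lineage medians at 4 and 8 h were positive with each array divided by its median, and quantile normalization turned the 24 h medians of Th17 to 0.01 and of heat shock to -0.07.

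At 24 h limma called 187 probe sets (126 genes) higher and 332 (210 genes) lower, of 3207 with an unadjusted p under 0.05, and camera placed 11 lists higher and 6 lower. Of these lists 0 held with an estimated correlation. Without either 0 h array limma called 0 and 0, without either 4 h array 3 and 0, without either 8 h array 3 and 7, without the knockout-labelled 24 h array 38 and 95, and without the wild-type-labelled one 479 and 644. With each array divided by its median, which moved the median change from -0.07 to 0.15, the calls were 351 and 224.

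From 4 to 24 h limma called 9 probe sets higher and 9 lower (4 and 8 genes), of 1813 with an unadjusted p under 0.05. The genes are named here after their values were seen. Gzmb (4.79), Lag3 (3.47), Zmat3 (3.04) and Tpi1 (2.81) rose. Igha (-5.52), S100a8 (-4.54), Igkv9-120 (-3.85), Iglv1 (-3.72), Tnf (-3.38), Ms4a6c (-2.35), Egr2 (-2.09) and Sun2 (-1.86) fell, with limma adjusted p from 0.0198 to 0.0493. Camera placed 3 lists higher, led by glycolysis (median 1.38; adjusted p = 2.25e-09, and adjusted p = 0.614 with an estimated correlation). It placed 9 lower, led by granulocyte markers (median -2.96; adjusted p = 9.65e-12, and adjusted p = 0.614 with an estimated correlation). The p53 response (1.11) and cholesterol synthesis (0.29) were also higher, with camera adjusted p of 0.00168 and 0.0453, and adjusted p = 0.862 and 0.87 with an estimated correlation. B cell markers (-0.70) and the Gfi1 targets (-0.92) had camera adjusted p of 1.05e-06 and 0.000358, and adjusted p = 0.614 with an estimated correlation. NF-kB (-0.63), mitosis (-0.86), interferon (-0.66), amino acid (-0.59), monocyte (-0.44) and early activation genes (-0.78) had camera adjusted p of 0.000358, 0.00165, 0.00165, 0.00209, 0.00977 and 0.0101, and adjusted p = 0.862 with an estimated correlation for each. The median and mean differed in sign for the cytotoxic list (-0.31 and 0.09), regulatory T cells (0.21 and -0.01), the CD4 lineage (-0.15 and 0.21, with a median of 0.03 when each array was divided by its median) and heat shock (0.23 and -0.02). Adjusted over the list alone 8 glycolysis genes were higher, 7 p53 response genes higher and 1 lower, and 9 granulocyte, 6 B cell and 5 monocyte markers, 6 Gfi1 targets and 5 NF-kB, 5 early activation and 4 interferon genes lower. Without the wild-type-labelled 24 h array limma called 27 and 29, without each other array in turn 0 and 0, and with quantile normalization 1 and 5.

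The third comparison asks whether the response differed between genotypes, by size alone and without a test. At 4 h the 5 genes furthest ahead in the knockout-labelled array were Ptgs2, Il1b, Saa3, Acod1 and Cxcl11. The prostaglandin synthase Ptgs2 changed by 5.03 against 0.43, the interleukin Il1b by 4.27 against -0.31, the acute phase protein Saa3 by 5.55 against 1.06, the itaconate-producing enzyme Acod1 by 6.73 against 2.29 and the chemokine Cxcl11 by 5.70 against 1.42. Il4 changed by 0.42 against 5.09, Prnp by 0.92 against 4.39, the AP-1 factor Fosb by -2.13 against 1.29, the nuclear receptor Nr4a3 by 0.39 against 3.27 and Hilpda by -0.03 against 2.84. Among the lists, early activation genes had 4 of 24 members at least 4-fold behind and 0 ahead, and interferon genes 4 of 22 ahead. Monocyte markers were 1.49 higher in the same knockout-labelled array. In all, 120 probe sets (74 genes) were at least 4-fold ahead in the knockout-labelled array and 52 (22 genes) behind, and with each array divided by its median 96 and 72.

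At 8 h Il1b and Cxcl11 were again among the 5 genes furthest ahead, with Cfb, Ly6i and Fpr2. Il1b changed by 4.82 against -0.94, the complement factor Cfb by 5.44 against 0.00, Cxcl11 by 6.44 against 1.13, Ly6i by 4.8 against 0.00 and the formyl peptide receptor Fpr2 by 4.6 against 0.13. Il4 changed by 0.00 against 4.31, with both knockout-labelled signals at the floor, Fosb by -2.95 against 1.19, the amino acid transporter Slc7a5 by 0.63 against 4.18, Polr2a by -2.46 against 0.78 and Gm6958 by -0.27 against 2.74. Irf4, an early activation factor, changed by 3.36 against 6.01, and 8 of 22 interferon genes were at least 4-fold ahead, Ifit2 by 3.41 against -0.63. The median of cholesterol synthesis genes changed by 1.35 against 0.05, with Hmgcs1 at 2.78 against 0.53. Over all probe sets 249 (152 genes) were ahead and 102 (58 genes) behind. Monocyte markers were 2.26 higher in the same knockout-labelled array.

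At 24 h 12 of 22 interferon genes were at least 4-fold ahead in the knockout-labelled array. Rsad2 changed by 4.66 against -1.34, Ifit1 by 3.16 against -1.54 and Mx1 by 2.70 against -1.24. The transglutaminase Tgm2 changed by 4.96 against -0.72, the receptor component Ramp3 by 4.58 against -0.63, the scavenger receptor Cd36 by 3.47 against -1.58 and Acod1 by 5.38 against 0.60. Monocyte markers were 2.05 higher in the same knockout-labelled array, with 12 of 18 at least 2-fold higher. DNA replication genes had 17 of 24 members at least 4-fold behind, with a median change of -1.60 against 0.72. Tk1, thymidine kinase, changed by -3.75 against -0.26, Mcm5 by -1.97 against 1.43, the nuclease Exo1 by -2.55 against 1.33 and Cdca7 by -2.29 against 1.38. Slc7a5 changed by -1.61 against 2.86, Hp by -5.51 against -0.71 and B4galt6 by -4.09 against -0.37. Resting T cell genes were ahead in 9 of 20 cases, with the homing receptor Ccr7 at 4.24 against 0.49. T cell identity genes had a median change of 1.00 against -0.405, with 1 of 16 at least 4-fold ahead. Granulocyte markers had -3.79 against -2.80, with 4 of 13 at least 4-fold behind. Since 12 of the 13 wild-type-labelled signals were at the floor at 24 h, the wild-type value is limited by it. Over all probe sets 500 (306 genes) were ahead and 363 (217 genes) behind, and with each array divided by its median 354 and 530. Across genes, which are not independent replicates, the changes in the 2 genotypes correlated at r = 0.59 at 4 and 8 h and 0.45 at 24 h.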

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

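The rule used here, a change from 0 h of at least 1 on the log2 scale in opposite directions in the 2 genotypes (0.5 for a list's median), and all values in this part were chosen after genotype values had been seen. It was applied only to the gene lists and to genes that the fixed naming rule picked for a difference in response, so other genes can meet it. The differences were not tested, since each rests on 1 array per genotype and time. At 4 h Fosb changed by -2.13 in the knockout-labelled and 1.29 in the wild-type-labelled arrays (difference -3.42), and Ifit2 by 1.17 and -1.11 (2.28). At 8 h Fosb changed by -2.95 and 1.19 (-4.13) and Gata3 by -1.11 and 1.46 (-2.57).

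At 24 h the interferon-induced Rsad2, Ifit1 and Mx1 differed in their change by 6.00, 4.70 and 3.94, with increases in the knockout-labelled arrays and decreases in the others. Cd36 (5.04), Klrc1 (3.74), Tnfaip3 (3.45), Rora (2.98), Anxa2 (2.82), Id2 (2.73), Thy1 (2.48) and Trp53inp1 (2.17) went the same way. Slc7a5 (-4.47), Exo1 (-3.88), Cdca7 (-3.675), Gins1 (-3.49), Mcm5 (-3.40) and E2f1 (-3.32) went the other way, and so did the DNA replication list, with a median difference of -2.28 from changes of -1.60 and 0.72.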

How the results depend on the processing

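The alternative relative to the T cell identity list was chosen after the result was seen and the others were planned. Counts are given as higher and lower in knockout-labelled arrays, or after stimulation, and the cause of a move was not tested except where given. Of the alternative counts 171 moved and 191 were the same. Among called genes 2312 values were the same, 1397 weaker and 1 reversed, and among called lists 786 were the same, 58 weaker and 4 reversed. Where the signal over background is small, at or near the floor, a difference is at best a lower bound.

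With the floor at the 20th percentile the genotype rule was met by 373 and 41. At single times 1786 and 2201 probe sets differed at 0 h, 2398 and 2127 at 4 h, 2921 were lower at 8 h, and 2955 and 1349 differed at 24 h. Response differences numbered 456 and 281 at 4 h, 606 and 499 at 8 h and 1278 and 626 at 24 h. Lower calls were 32 at 4 h and 37 from 4 to 24 h, and 6 lists were lower at 4 h. With the floor at the 60th percentile the rule was met by 75 and 8. At single times 613 and 596, 879 and 655, 876 and 489, and 597 and 462 differed. Stimulation gave 51 and 24 at 4 h, 65 and 51 at 8 h, 78 and 88 at 24 h and 1 and 1 from 4 to 24 h, with 4 lists lower at 8 h. Response differences numbered 49 and 31, 130 and 37, and 266 and 226.

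With log2 of the signal plus the floor value 14 probe sets met the rule as lower, and 674, 674, 576 and 453 were lower at 0, 4, 8 and 24 h. Response differences were 58 and 21, 144 and 38, and 305 and 192, and calls from 4 to 24 h were 19 and 37. Dividing each array by its median gave 47 lower by the rule, 1599 lower at 24 h, 45 and 94 lower calls at 4 and 8 h, 351 higher calls at 24 h and 5 lists lower at 4 h. Quantile normalization gave 45 and 94 lower calls at 4 and 8 h, 1 and 5 from 4 to 24 h and 6 lists lower at 4 h. Without the filter calls were 5 and 11 at 4 h, 3 and 10 at 8 h, 3 and 14 at 24 h and 0 and 0 from 4 to 24 h, with 5 lists lower at 4 h and prior degrees of freedom of 0.74. Without the genotype block they were 34 and 34, 45 and 53, 38 and 53, and 0 and 0. Without the variance trend calls from 4 to 24 h were 1 and 2.

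By construction other fold thresholds moved the counts, to 485 and 150 at 1.5-fold and 99 and 6 at 3-fold for the rule, and to 1155 and 924, 1508 and 1226, and 2333 and 1917 for 2-fold response differences. limma with time as a block, which takes the 4 times of 1 source per genotype as replicates, gave 401 and 82, sharing 236 of the 240 and 22 of the 23. Relative to the T cell identity list 1339 and 0 met the rule, with 240 of 240 and 0 of 23 shared. That list's median difference was negative at all 4 times, which raises every difference, so the 240 were kept by construction. Leaving out 1 time gave 249 to 535 and 29 to 200, the highest without the 24 h pair, and 435 and 56 without the 0 h pair.

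Leaving out 1 array gave 0 to 175 higher and 0 to 91 lower calls at 4 h, 0 to 286 and 0 to 368 at 8 h, 0 to 479 and 0 to 644 at 24 h and 0 to 27 and 0 to 29 from 4 to 24 h. Lists lower by camera numbered up to 5 at 4 h, without the knockout-labelled 0 h or the wild-type-labelled 4 h array. At 8 h they numbered 2 to 7, with 2 without the wild-type-labelled 0 h array and 7 without the knockout-labelled 8 h array.

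Directions of some list medians reversed without 1 array. The p53 list at 8 h ranged from -0.0844 (without the wild-type-labelled 8 h array) to 0.573, and was -0.0046 without the knockout-labelled 0 h array. Ribosome biogenesis at 4 h ranged from -0.0752 (without the wild-type-labelled 0 h array) to 0.926. DNA replication at 24 h ranged from -1.61 to 0.672 and regulatory T cell genes from -0.0284 to 1.08, with DNA replication positive and regulatory T cell genes negative without the knockout-labelled 24 h array. Th17 at 24 h ranged from -0.107 to 0.892 (without the wild-type-labelled 24 h array), and was 0.405 without the wild-type-labelled 0 h array. The response difference of Csf1r at 24 h reversed to -1.27 with the median over its probe sets.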

Other observations

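All tests below were chosen after the result was seen, except those of the scaling of the arrays for the granulocyte and DNA replication lists. The first pattern is the higher granulocyte and monocyte genes and lower T cell genes in the knockout-labelled arrays. A lower T cell share that raises every other cell type alike is argued against by the B cell list, at -0.524 at 0 h against 2.74 for the granulocyte list (larger SD over members 1.94), and the scaling by a lowest granulocyte median of 3.101 under 2 other scalings. Granulocyte precursors and monocytes in the preparation are a candidate source that no value here decides, since the T cell identity median of -1.466 at 0 h is part of the pattern itself; in the knockout-labelled 0 h array Mpo gave a signal of 33134 and Prtn3 23387. The pan-T cell enrichment would be meant to remove such cells, all 13 genes were above the floor in the wild-type-labelled 0 h array, and Elane is also on the Gfi1 target list. Expression of these genes within T cells that lack Gfi1 stays open, with 1 source number per genotype.

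The second pattern is lower Il4 and higher Il17a after stimulation. A lower T cell share would lower T cell genes about as much as Il4. Il4 lay at -3.173 relative to the T cell identity median and Il17a at 5.03 over it (SD 0.62 over the list's 16 members and 1.05 over the 22 other cytokine genes). Both genes were chosen because they differed, so a large distance from the list followed from that choice and does not decide the explanation. The knockout-labelled Il4 signal at 8 h was at the floor. For Il4, the scaling and the floor are argued against by its smallest mean difference over 4, 8 and 24 h under 6 alternatives, -3.184 against -4.27. A change in T cell subsets or in cytokine control without Gfi1 may explain it, and neither was tested.

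The third pattern is lower DNA replication genes in the knockout-labelled 24 h array. For loss of other cycling cells, the list median was -1.176 relative to the T cell identity list (SD over members 0.67). The mitosis list at 24 h had a median difference of -0.743 (SD over members 0.476) against -0.287 for T cell identity. The T cell identity list does not measure how many other cycling cells were present or lost, so this test does not decide it. An exchange of the 24 h arrays is argued against by 60 probe sets that met the rule with those labels exchanged, against 263, and the scaling by a smaller median of -1.413. A weaker or earlier division of these T cells may explain it, as a hypothesis, and culture conditions of this single array stay open. For the 263 probe sets, the 8 exchanges of labels within times are too few for a share under 0.05, with 1 as large, the real one, and 60 as the highest other.

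Some genes outside the lists were noted after their values were seen. The mast cell and basophil proteases Mcpt8 and Cpa3 were higher in the knockout-labelled arrays by 2.67 and 2.59 on average, and the progenitor antigen Cd34 by 2.81. At 24 h the hypoxia-responsive Bnip3 gave 13923 against 522, and Ndrg1, Egln3 and Hilpda were higher by 3.45, 2.43 and 2.29. The metallothionein Mt1 was higher by 0.86, 2.87, 2.67 and 2.86. None of these differences was tested.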
